A study of Mus musculus with 19 samples.

How the data were processed

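The series measured polyadenylated RNA of C57BL/6 mouse cells by Illumina sequencing, in a retroviral and a knock-in model of leukemia driven by an internal tandem duplication of the receptor tyrosine kinase FLT3 (FLT3-ITD). RNA was extracted with the Qiagen AllPrep kit and libraries were made with the TruSeq kit after polyA selection, per the labels' protocols. In the retroviral model, donor marrow with or without the de novo DNA methyltransferase gene Dnmt3a was transduced with FLT3-ITD-GFP or GFP alone and transplanted, and donor-derived CD4+CD8+ cells were sorted from thymus or marrow. In the knock-in model, the duplication sits in the mouse Flt3 gene and bulk marrow was collected without a sort. The 19 GEO samples are 17 libraries, because the technical runs of each wild-type GFP library share 1 deposited value. Each library was placed in 1 of 7 groups from its labelled genotype, and no column was left without a label. The retroviral groups are called WT-GFP, KO-GFP, WT-ITD and KO-ITD here, for wild-type or deleted Dnmt3a and for GFP alone or FLT3-ITD; the knock-in groups are called pre-leukemic, Dnmt3a f/+ and Dnmt3a f/f, where f is the floxed allele. The pre-leukemic group is also f/f but lacks Cre, and is treated as having intact Dnmt3a. The labels call the replicates biological, but do not tie each one to an animal, so the p-values measure the spread between these samples.

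The main values are estimated counts of fragments per gene, which the authors deposited in 1 table for all 17 libraries and which are not scaled for depth. Per the submitters' processing notes, reads were aligned to the mouse genome build mm9 with TopHat2 2.0.10 and processed with Cufflinks 2.1.1 (for the later records the Cufflinks version is not given) and Cuffdiff 2.1.1 or 2.2.1. Which step wrote the count table, whether strand was used and which filters were applied are not given in the sources used here. Genes that overlap on opposite strands or share sequence with close paralogs, such as the Klra, Ly6, H2-Q and Hba families, are therefore uncertain. The table has 23458 gene names, and 133 of them lie on more than 1 chromosome or strand in the deposited gene models. Coordinates are those of the deposited gene models on mm9, 1-based. The authors also deposited FPKM values (fragment counts scaled for gene length and depth) for 9 libraries, in a separate file for each library, with loci assembled in that library alone. At least 98.95% of the FPKM sum in each file lay in assembled loci without a gene name, and 2395 to 4459 named genes were above 0, so FPKM values were matched to genes by the position of the gene models.

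Between 98.12% and 98.54% of the nonzero estimated counts were whole numbers within a tolerance of 0.001, and the values were rounded to whole numbers. The design fixed before the data were examined kept the first 5 comparisons (those within the retroviral model) on FPKM unless the count table held raw whole-number counts. The deposited counts did not strictly meet that condition, so using them as the main values is a departure from the plan. It was made once the files had been seen and before any test was run, because the FPKM files are separate assemblies of 9 libraries and cover only part of the named genes. The planned test, limma 3.58.1 with a trend on log2(FPKM + 1) of 3914 genes, is reported beside each of these 5 counts, and its fold changes are on that log2 scale. The other 4 comparisons were planned on counts. Each FPKM file correlated best, across genes, with the count column of its own library in 9 of 9 cases (r of 0.771 to 0.898, against at most 0.717 with another library).

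Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low genes were removed with filterByExpr at its default settings, which left 15508 genes. Libraries were scaled by the trimmed mean of M-values (factors 0.943 to 1.076), and edgeR's quasi-likelihood model was fitted once to all 17 libraries with 1 mean per group. Each comparison is a contrast of that fit, tested two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit shares 1 estimate of the spread across groups, so that a group with 1 library is assumed to vary like the others. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are given as CPM, counts divided by the scaled library size and multiplied by 1e6, as mean ± SD over libraries. A gene with no counts on its lower side is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts it is given as a ratio with a 95% exact binomial counting interval, which covers counting error only. Levels of gene lists are means of log2 CPM with a prior count of 2.

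The text names, per comparison, the 8 genes with the largest rise and the 8 with the largest fall that passed the threshold, had a mean of at least 5 CPM in the higher group and showed no overlap between the groups' libraries, leaving out predicted and numbered gene names. It also names up to 4 members of each gene list with the smallest p, and always Dnmt3a, Dnmt3b, Flt3, Cd4 and Cd8a. Some results were left out because they were withheld for evaluation. The 23 gene lists (566 entries, some genes in more than 1 list) hold cell type markers and pathways, including markers of cell types that a CD4+CD8+ sort should remove. They, the groups, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists of a comparison, and again with an estimated correlation. With the estimated correlation, only the list of CD4+CD8+ thymocyte genes in the comparison of the models stayed past the threshold. List members are counted over all genes tested and, separately, adjusted over the list alone.

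Total counts ran from 4933890 to 25331908 per library. The common dispersion was 0.276, a biological coefficient of variation of 0.525. The code was tested on simulated counts for each comparison, with 67, 67 and 66 genes changed 2-fold, 4-fold and 8-fold. Counts were drawn from each gene's mean over all libraries, its dispersion and the libraries' sizes. For KO-ITD against KO-GFP (14932 genes) edgeR recovered 7.5%, 31.3% and 68.2% of them. For WT-ITD against WT-GFP (14917 genes) it recovered 6%, 28.4% and 60.6%, and for KO-ITD against WT-ITD (14914 genes) 10.4%, 44.8% and 53%, with 3 false calls among 75. For KO-GFP against WT-GFP (14948 genes) it recovered 1.5%, 38.8% and 50%, and for the interaction (14926 genes) 0%, 13.4% and 43.9%. For the Dnmt3a f/f against the Dnmt3a f/+ knock-in leukemias (14931 genes) it recovered 0%, 14.9% and 30.3%, so that 2-fold changes are mostly below what these designs can show. In the same simulation of KO-ITD against WT-ITD, DESeq2 made 55 false calls among 150 and limma voom 2 among 74. The simulated groups have the same spread, whereas the real median SD of log2 CPM ran from 0.122 (WT-GFP) to 0.585 (KO-ITD). Recovery and false calls in the real data may therefore differ from these values.

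Alternatives fixed before the data were examined were the leaving out of each library (except the only Dnmt3a f/f library), a fit without the filter on low counts, a fit on only the groups compared, tissue as a covariate, marrow or thymus libraries alone, a replicate block, other settings of the FPKM test and, for the knock-in comparisons, DESeq2 1.42.0 and its size factors. Alternatives added later were DESeq2 and its size factors for the retroviral comparisons, a minimum of 5 CPM, limma voom, counts of the 9 libraries with FPKM values, and libraries of the second submission alone. The deposited transcript-level counts were not used here.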

Results

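Expression was measured in 17 libraries from 2 mouse models of FLT3-ITD leukemia. The retroviral model gave sorted CD4+CD8+ cells of transplant recipients: normal thymocytes carrying GFP alone with wild-type Dnmt3a (WT-GFP, n = 2) or deleted Dnmt3a (KO-GFP, n = 2), and leukemias carrying FLT3-ITD with wild-type (WT-ITD, n = 3) or deleted Dnmt3a (KO-ITD, n = 4). CD4+CD8+ thymocytes are the double-positive stage of T cell development. The knock-in model gave unsorted marrow with 1 Flt3 allele carrying the duplication: pre-leukemic marrow with 2 floxed Dnmt3a alleles but without Cre recombinase (n = 3), leukemias in which Cre could delete 1 Dnmt3a allele (Dnmt3a f/+, n = 2) and 1 leukemia in which it could delete both (Dnmt3a f/f, n = 1). The GFP libraries came from thymus, WT-ITD replicates 1 and 3 from thymus and replicate 2 from marrow, and KO-ITD replicates 1 and 2 from marrow and 3 and 4 from thymus. KO-ITD replicates 3 and 4 and all knock-in libraries belong to a second submission. Donor cells were enriched for Sca-1 for all KO-ITD libraries and for ckit for both KO-GFP libraries. WT-ITD replicates 1 to 3 came from Sca-1 cells, ckit cells and whole marrow, and for WT-GFP the enrichment is not given. Total counts were 25034309 and 25331908 for WT-GFP, 16606964 and 19516952 for KO-GFP and 20015543, 16830729 and 16295347 for WT-ITD. They were 8184576, 18620967, 8597919 and 7660541 for KO-ITD and 5253574, 4933890 and 22347359 for pre-leukemic marrow. The Dnmt3a f/+ leukemias had 15451455 and 14564553 and the Dnmt3a f/f leukemia 19493377. Values are CPM as mean ± SD over n libraries. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

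The targeted gene, Dnmt3a (chromosome 12, 3806980 to 3914443, plus strand, mm9), was at 257.2 and 250.1 CPM in the WT-GFP libraries and at 207.1 and 144.2 CPM in the KO-GFP libraries. In the WT-ITD leukemias it was at 180.2, 237.7 and 182.7 CPM. In the KO-ITD leukemias it was at 65.8, 126.7, 68.07 and 53.03 CPM. Pre-leukemic marrow had 129.6, 153.5 and 143 CPM, the Dnmt3a f/+ leukemias 54.96 and 47.37 CPM, and the Dnmt3a f/f leukemia 36.46 CPM. Every library labelled with a floxed allele and Cre lay below every library of its reference group, the wild-type group with the same transgene in the retroviral model and the floxed marrow without Cre in the knock-in model. The gene-level count includes exons outside the deleted part, so it checks the labels only in part. The labels do not give the sex of the animals, and no fit adjusts for it. Xist, a gene of the inactive X chromosome chosen here after its values were seen, was at 1463 and 1655 CPM in WT-GFP and 2839 and 1802 CPM in KO-GFP. It was at 0.05, 1.59 and 1234 CPM in WT-ITD, at 0, 2276, 0 and 0 CPM in KO-ITD and at most 2.26 CPM in the knock-in libraries. The Y chromosome gene Ddx3y, chosen likewise, was at most 0.06 CPM in the 6 libraries that expressed Xist and at least 83.5 CPM in the other 11. All GFP libraries but only WT-ITD replicate 3 and KO-ITD replicate 2 among the retroviral leukemias expressed Xist, so sex stays untested as a source of differences between leukemias and GFP thymocytes. Leaving out each of these 2 leukemias gave the highest count of its comparison with GFP thymocytes (607 and 3954).

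**Figure D1:**
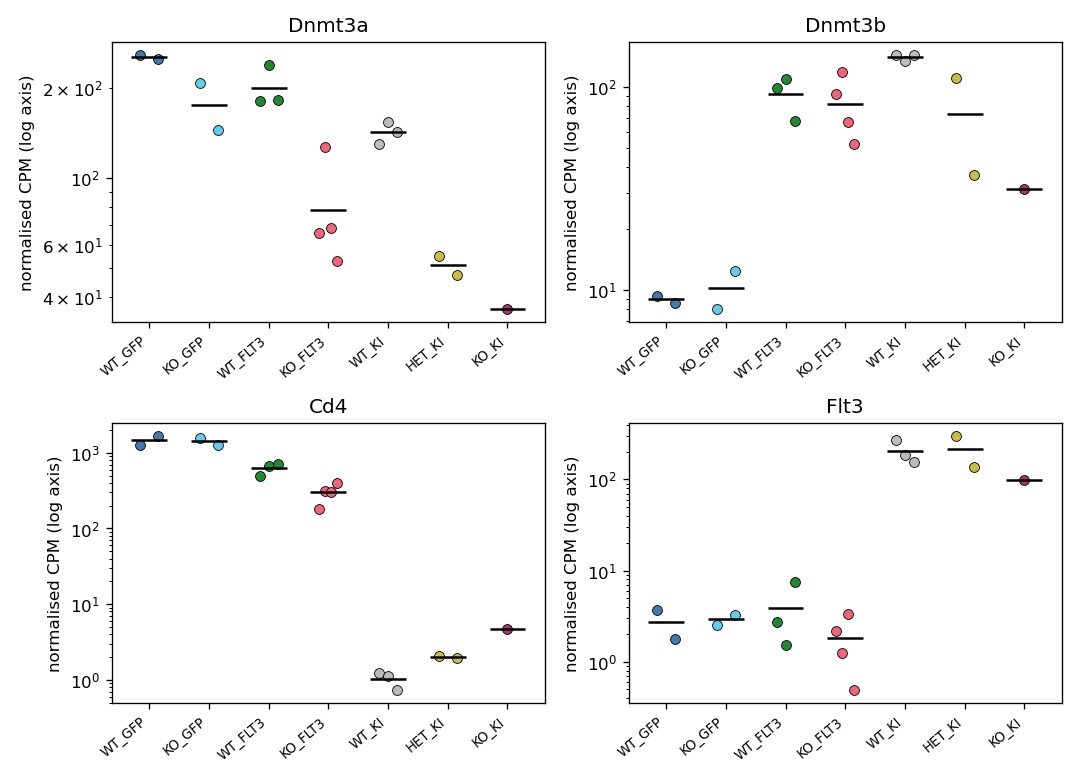
Normalised CPM (log axis) of Dnmt3a, Dnmt3b, Cd4 and Flt3 in each library (points) by group, with a bar at the group mean. Dnmt3a runs from 36.46 CPM in the Dnmt3a f/f knock-in leukemia to 257.2 CPM in a WT-GFP library.

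Libraries separated by model on the first principal component of log2 CPM, which held 44.1% of the variance. All knock-in libraries lay below -120 there, and the retroviral ones between -30.5 and 137.3. The second component held 17%. It had the 4 GFP libraries between -73.3 and -63.5 and KO-ITD replicate 4 at 150.6, with the other KO-ITD libraries between 49.7 and 87.1. Across genes, log2 CPM correlated at 0.992 between the WT-GFP libraries, 0.99 between the KO-GFP libraries, 0.933 to 0.977 among WT-ITD and 0.872 to 0.968 among KO-ITD leukemias (genes are not independent replicates). No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom of at least 8.83.

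**Figure D2:**
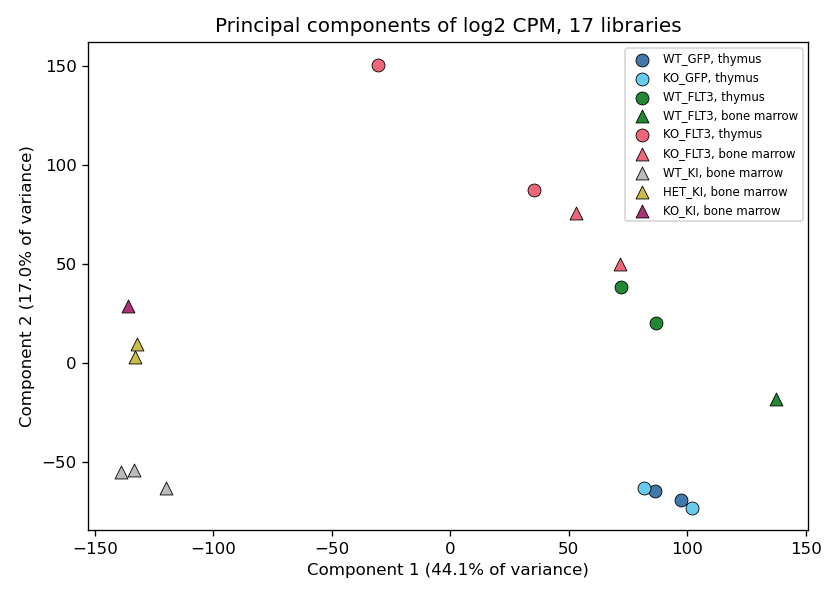
Scores of the 17 libraries (points, coloured by group) on the first and second principal components of log2 CPM, in arbitrary score units. The first component (44.1% of the variance) separates the knock-in from the retroviral libraries, and the second (17%) runs from the GFP thymocytes to KO-ITD replicate 4.

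The effect of FLT3-ITD with intact Dnmt3a was asked by setting WT-ITD leukemias (n = 3) against WT-GFP thymocytes (n = 2). Il2ra, the alpha chain of the interleukin-2 receptor (chromosome 2, 11564419 to 11614821), was at 2389 ± 1168 CPM against 50.2 ± 7.39 (log2 fold change 5.57, SE 0.98, adjusted p = 0.0121). The Notch targets Heyl (log2 fold change 6.95), Hes1 (3.06) and Myc (1.71, 148 ± 22.3 against 45.4 ± 5.81 CPM) rose with it, at adjusted p = 0.0227, 0.0286 and 0.0123. Dnmt3b, the other de novo methyltransferase (chromosome 2, 153475185 to 153513466), rose from 8.98 ± 0.49 to 91.6 ± 21.3 CPM (log2 fold change 3.35, SE 0.48, adjusted p = 0.00335). Cd4 (chromosome 6, 124814711 to 124838227) fell from 1470 ± 269 to 621 ± 117 CPM (log2 fold change -1.24, SE 0.29, adjusted p = 0.0439), while Cd8a (-0.37, SE 0.55), Dnmt3a (-0.34, SE 0.30) and Flt3 (0.51, SE 0.68) did not pass the test, at adjusted p = 0.77, 0.597 and 0.736. Without WT-ITD replicate 3 the value of Flt3 was -0.33. Whether the Flt3 count includes reads of the retroviral transgene is not given in the sources used here.

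Of 16 Notch targets, 5 rose, none fell and 11 did not pass, with 10 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.05e-07, and adjusted p = 0.193 with an estimated correlation). Of 38 genes of double-positive thymocytes, 4 fell: Cd5, a restraint on T cell receptor signalling (-3.88), Rmnd5a (-1.98), the chromatin organiser Satb1 (-1.93) and Cd4. Adjusted over the list alone, 7 were lower and 1 higher (camera adjusted p = 1.42e-06, and adjusted p = 0.468 with an estimated correlation). All 28 MYC targets and ribosome biogenesis genes had a positive log2 fold change, but 1, Mybbp1a (1.04), passed the test over all genes and 5 over the list alone (camera adjusted p = 2.68e-08, and adjusted p = 0.78 with an estimated correlation). Of 23 genes of early T progenitors and CD4-CD8- thymocytes, 2 rose and none fell, 6 higher and 1 lower when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0583, and 0.78 with an estimated correlation). Among 30 genes induced or repressed downstream of FLT3, STAT5 or MAPK, 4 rose and 2 fell, and the list as a whole did not pass (camera adjusted p = 0.418). Those 4 include the STAT5-induced feedback regulator Cish (5.42) and the cytokine Osm (1.92), and the repressor Bcl6 (-4.35) is 1 of the 2 that fell. Adjusted over that list alone, 6 were higher and 10 lower. Camera tests for a shared direction, so its result for a list of induced and repressed genes does not show an unchanged pathway. Of 23 erythroid genes, 1 rose, the erythropoietin receptor Epor (7.09), and 11 were higher when adjusted over the list alone (camera adjusted p = 8.78e-06, and adjusted p = 0.78 with an estimated correlation). The list level was 4.87, 1.11 and 0.68 log2 CPM in the WT-ITD libraries, and without replicate 1 the list median fell from 4.13 to 0.862 (adjusted p = 0.00299). None of 27 granulocyte genes passed either adjustment, although camera called the list higher (adjusted p = 0.00143, and 0.828 with an estimated correlation), which was lost without WT-ITD replicate 1 (adjusted p = 0.288). None of 18 NK and cytotoxic genes passed over all genes and 3 were lower when adjusted over the list alone, and camera called this list lower (adjusted p = 0.00315, and 0.78 with an estimated correlation).

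The largest rises by the naming rule were Nov, a matricellular protein gene with no counts in WT-GFP (at least 3900-fold higher over the group), Necab1 (count ratio 1850, 95% counting interval 634 to 8990), Enah (1520, 420 to 12600), Crtac1 (635, 114 to 25100) and the growth factor receptor Egfr (log2 fold change 8.84). Without WT-ITD replicate 3 the ratio was 310 for Enah and 385 for Crtac1. The next largest rises were the secreted Wnt inhibitor Sfrp2 (8.79), Sall3 (8.64) and Ccdc136 (8.64). The largest falls were the Wnt ligand Wnt8b (count ratio 1100, 197 to 43500), the prohormone convertase Pcsk1 (-7.88), Zcchc12 (-7.74), Klra9 (296, 52.7 to 11700), Tox3 (272, 48.3 to 10800), Bahcc1 (-7.12), the heparan sulfate proteoglycan Gpc2 (-6.47) and Rbm24 (-6.27). Ctla4, an inhibitory receptor of T cells, rose by 5.57 on the log2 scale and the anti-apoptotic gene Bcl2 by 2.96. In all, 209 genes rose and 138 fell of 15508 (edgeR adjusted p below 0.05), and 326 of these 347 changed at least 2-fold. The planned limma test on FPKM called 312 of 3914 genes. DESeq2 called 1425 genes and limma voom 876. Most calls were of rises in DESeq2 (828 rose, 597 fell). They were of falls in limma voom (336 and 540) and on FPKM (136 and 176), so which direction prevails depends on the test. EdgeR on these 2 groups alone called 904, the libraries of the first submission 1268 and the thymus libraries 184. The count was 29 without WT-GFP replicate 1, 23 without WT-GFP replicate 2, 124, 184 and 607 without WT-ITD replicates 1, 2 and 3. Of 35 named genes Sfrp2, Bahcc1, Gpc2 and Cd5 passed whichever library was left out.

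The effect of FLT3-ITD with deleted Dnmt3a was asked by setting KO-ITD leukemias (n = 4) against KO-GFP thymocytes (n = 2). All KO-ITD libraries came from Sca-1 donor cells and both KO-GFP libraries from ckit donor cells, so that this comparison cannot separate FLT3-ITD from donor enrichment. Cd4 fell from 1412 ± 201 to 301 ± 90.3 CPM (log2 fold change -2.23, SE 0.27, adjusted p = 0.000564) and Cd8a from 1701 ± 138 to 531 ± 305 CPM (-1.68, SE 0.50, adjusted p = 0.0356). Dnmt3b rose from 10.2 ± 3.13 to 82.2 ± 29 CPM (3.01, SE 0.47, adjusted p = 0.0023), and Il2ra from 59.4 ± 13.3 to 1463 ± 632 CPM (4.62, SE 0.92, adjusted p = 0.00755). Dnmt3a fell by 1.16 on the log2 scale (SE 0.28, adjusted p = 0.0149). Flt3 was at 1.82 ± 1.24 against 2.92 ± 0.52 CPM and did not pass (adjusted p = 0.443).

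Of the 38 genes of double-positive thymocytes, 18 fell, 1 rose and 19 did not pass, with 19 lower and 1 higher when adjusted over the list alone (camera adjusted p = 5.04e-12, and adjusted p = 0.166 with an estimated correlation). They include Cd5 (-5.24), Cd6 (-5.00) and Rmnd5a (-2.36). Of 16 Notch targets, 11 rose and none fell, with 14 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.6e-05, and adjusted p = 0.313 with an estimated correlation), among them Heyl (6.30), Hes1 (3.91) and Myc (2.03). Of 23 genes of early T progenitors and CD4-CD8- thymocytes, 9 rose and none fell, 10 when adjusted over the list alone (camera adjusted p = 0.000479, and adjusted p = 0.454 with an estimated correlation), including the transcription regulators Lyl1 (2.92) and Lmo2 (3.85). This list was higher still in unsorted pre-leukemic marrow (6.42 to 6.63 log2 CPM, KO-ITD 3.24 to 4.28). Its rise therefore does not by itself show an earlier T cell stage. Of 28 MYC targets, 9 rose, 15 when adjusted over the list alone (camera adjusted p = 1.6e-05, and adjusted p = 0.813 with an estimated correlation), with the nucleolar methyltransferase Fbl at 1.23 and the spermidine synthase Srm at 1.43. Interferon response genes went the other way: 4 of 32 fell, with Ifit2 at -1.62 and the transcription factors Irf9 at -1.48 and Stat2 at -1.31, and 1 rose, Gbp3 (1.82), with the same counts when adjusted over the list alone (camera adjusted p = 0.0163, and adjusted p = 0.813 with an estimated correlation). Of 20 glycolysis genes, 6 rose, among them the isomerase Tpi1 (1.23) and Ldha (1.01), and adjusted over the list alone 6 were higher and 1 lower (camera adjusted p = 0.0495, and adjusted p = 0.813 with an estimated correlation). None of 36 cell cycle genes passed, while camera called the list lower (adjusted p = 0.0495, and 0.864 with an estimated correlation). That call rests on KO-ITD replicate 4. The list level was 7.42, 7.46, 6.98 and 4.98 log2 CPM in the KO-ITD libraries against 7.18 and 7.43 in KO-GFP. Without replicate 4 the list did not pass and was on the higher side (adjusted p = 0.893). It did not pass without KO-GFP replicate 2 either (0.3). The glycolysis list was lost in 4 of the 6 fits that leave out a library of these groups (adjusted p up to 0.158).

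Of 18 genes of thymic stroma, 8 rose and none fell, with 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.813 with an estimated correlation). Col1a1, a collagen chain of fibroblasts, was at 57.0, 31.6, 41.3 and 513 CPM in the KO-ITD libraries and at 1.10 ± 0.34 CPM in KO-GFP (log2 fold change 7.19, SE 1.65, adjusted p = 0.0123). The mesenchymal receptor Pdgfrb rose by 4.64. It was at 28.25, 18.69, 340.01 and 95.63 CPM in KO-ITD replicates 1 to 4, so replicate 3 carried most of its mean, and at 4.98 and 4.71 CPM in KO-GFP. Of 23 erythroid genes 9 rose, 17 when adjusted over the list alone (camera adjusted p = 1.6e-05, and adjusted p = 0.785 with an estimated correlation), with the red cell anion exchanger Slc4a1 at 8.96 and the erythroid factor Gata1 at 4.66. Of 15 megakaryocyte genes 5 rose, 9 when adjusted over the list alone (camera adjusted p = 0.00253, and adjusted p = 0.785 with an estimated correlation), with the platelet factor gene Pf4 at a count ratio of 251 (95% counting interval 85.6 to 1220), or 31.9 without KO-ITD replicate 4. Of 27 granulocyte genes 2 rose, Hp (8.01) and Prtn3 (3.59), and of 24 monocyte and macrophage genes 2 rose, Hmox1 (6.20) and Klf4 (5.98). Adjusted over the list alone 0 granulocyte genes and 1 monocyte gene passed, and both lists passed camera (adjusted p = 0.000862 and 0.012, and 0.813 for both with an estimated correlation), the monocyte list not without KO-ITD replicate 4 (0.0813). The NK (1 rose and 1 fell of 18), dendritic cell and MHC class II (1 fell of 20) and B cell (1 rose of 19) lists did not pass, at camera adjusted p = 0.447, 0.407 and 0.702 and 0.864 for each with an estimated correlation. Adjusted over the list alone, the counts were the same for the first 2 and 0 for B cells.

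By the naming rule, the largest rises were in the matrix and serum protein genes Sparc (at least 1030-fold over the group), Serping1 (at least 584-fold), Lyve1 (at least 495-fold), Serpina3n (count ratio 5370, 964 to 212000), Mgp (at least 388-fold) and Bgn (2920, 524 to 115000). Without KO-ITD replicate 4, the values of these 6 genes were 384, 192, 24.7, 263, 99.2 and 1380, so that their size rests largely on that library. Others were in the erythroid gene Rhag (at least 331-fold, and 90.4-fold without KO-ITD replicate 2) and the glycine decarboxylase Gldc (log2 fold change 10.85). The largest falls were the calcium channel Cacna1e (-9.28), Zcchc12 (-7.25), Smoc1 (-6.90), Rbm24 (-6.46), the cytotoxic cell receptor Klrk1 (count ratio 90.7, 30.6 to 443, and 37.2 without KO-GFP replicate 2), Pcsk1 (-6.07), Gpc2 (-5.81) and Wnt8b (-5.75). The cytotoxic protease Gzma rose by 4.51 on the log2 scale, Ctla4 by 4.25, Bcl2 by 3.18 and Bax by 1.36. The chemokine receptor Ccr9 (-4.96) and the early response gene Nr4a1 (-3.57) fell. In all, 1520 genes rose and 1527 fell (edgeR, 2211 of the 3047 by at least 2-fold), and the planned limma test on FPKM called 958. DESeq2 called 5015 genes (2996 rose, 2019 fell), limma voom 3160 (1333 and 1827), edgeR on these 2 groups alone 439, and the libraries of the first submission alone 3635. The count was 147 without KO-GFP replicate 1 and 917 without KO-GFP replicate 2. Of 56 named genes Cacna1e, Zcchc12, Gpc2, Osm, Bcl6, Cd5, Rmnd5a, Nr4a1 and Cd4 passed whichever library was left out.

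Whether FLT3-ITD acted differently with and without Dnmt3a was tested as the interaction of both factors in the same fit. Donor enrichment and submission also differ between these groups, and the interaction cannot separate them from Dnmt3a. The interaction was -0.99 (SE 0.40) for Cd4, -0.82 (SE 0.42) for Dnmt3a, -0.34 (SE 0.58) for Dnmt3b, -1.22 (SE 0.95) for Flt3 and -1.31 (SE 0.76) for Cd8a on the log2 scale, and none passed (edgeR adjusted p = 0.819, 0.819, 0.931, 0.825 and 0.819). Dnmt3b was at 0.01 without KO-GFP replicate 2 and at 0.00 in the libraries of the first submission. No gene passed in edgeR, where 838 had an unadjusted p below 0.05 and the smallest adjusted p was 0.299. The planned limma test on FPKM and limma voom also called 0, DESeq2 80 and the libraries of the first submission 13, and without WT-ITD replicate 3 edgeR called 39. By direction, 174 genes rose in both comparisons with GFP thymocytes, against 20.5 expected of independent lists, and 104 fell in both, against 13.6 expected. The comparisons share no library, but both come from 1 fit with the same spread per gene, so their calls are not fully independent. In both, most leukemias lacked Xist while the GFP thymocytes expressed it, so a part of sex in this overlap is untested. Camera called 8 lists in the interaction, with no member passing over all genes. Of these the monocyte and macrophage (median 3.13, adjusted p = 2.49e-07), early T progenitor (1.32, 0.0041), megakaryocyte (1.78, 0.0128), NK (0.972, 0.0435) and p53 target (0.438, 0.0408) lists were higher. Those of double-positive thymocytes (-0.453, 1.31e-05), the cell cycle (-0.326, 0.0041) and the interferon response (-0.589, 0.00698) were lower. With an estimated correlation the adjusted p was 0.728 for the early T and double-positive lists, 0.832 for the monocyte list and 0.93 for the other 5, and adjusted over the list alone 1 early T gene was higher. Only the monocyte and double-positive lists passed whichever library was left out, and the monocyte median fell to 1.00 without KO-ITD replicate 4. The medians without that library were 0.739 for the early T and 0.951 for the megakaryocyte list, and that of the NK list was 0.283 without KO-ITD replicate 3. Without WT-ITD replicate 3 the interferon list was on the higher side (adjusted p = 0.917), and without KO-ITD replicate 4 the cell cycle list did not pass (0.88).

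The effect of Dnmt3a loss among leukemias was asked by setting KO-ITD (n = 4) against WT-ITD (n = 3). All KO-ITD libraries came from Sca-1 donor cells, whereas WT-ITD came from Sca-1 cells, ckit cells and whole marrow. KO-ITD replicates 3 and 4 are also the only libraries here of the second submission. Donor enrichment and submission can therefore not be fully separated from genotype in this comparison. Dnmt3a fell from 200.2 ± 32.5 to 78.4 ± 32.9 CPM (log2 fold change -1.35, SE 0.25, adjusted p = 0.0353), and Tet1, which oxidises methylated cytosine (chromosome 10, 62267318 to 62342762), from 94.8 ± 32.7 to 35.6 ± 8.99 CPM (-1.41, SE 0.25, adjusted p = 0.0293). Dnmt3b did not pass (82.2 ± 29 against 91.6 ± 21.3 CPM, log2 fold change -0.16, SE 0.35, adjusted p = 0.834), nor did Flt3 (-1.13, SE 0.60, adjusted p = 0.299), Cd4 (-1.05, SE 0.24, adjusted p = 0.0781) or Cd8a (-1.40, SE 0.46, adjusted p = 0.154). The direction of Dnmt3b turned positive without KO-ITD replicate 4 (0.01) and in the libraries of the first submission (0.20), and that of Flt3 in marrow libraries alone (0.02). Kank4 (chromosome 4, 98421583 to 98484228) had the largest rise, from 0.098 ± 0.074 to 132 ± 96 CPM (10.32, SE 1.28, adjusted p = 0.00553), ahead of Pdgfrb (7.68), the ceramide synthase Cers4 (6.10), the calcium pump Atp2a1 (5.35), Zfp783 (5.14), Cd93 (4.77), Trim16 (4.72) and Chst11 (4.28). Pdgfrb was at 28.25, 18.69, 340.01 and 95.63 CPM in KO-ITD replicates 1 to 4 and at most 0.86 CPM in WT-ITD. The largest falls were Mum1l1 (chromosome X, 135744583 to 135772874; count ratio 232, 95% counting interval 79 to 1130), Cacna1e (-6.78), the splicing regulator Esrp1 (-5.98), Sall3 (-4.38), Lmo4 (-3.78), Slco3a1 (-3.71), Cd6 (-3.15) and the cadherin Cdh24 (-3.10). Id1, an inhibitor of helix-loop-helix factors, rose by 3.73 and the B cell gene Bank1 fell by 2.73 on the log2 scale.

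Among the lists, 1 of 38 genes of double-positive thymocytes fell (Cd6) and 34 of 38 had a negative log2 fold change, with 4 lower when adjusted over the list alone (camera adjusted p = 2.39e-08, and adjusted p = 0.44 with an estimated correlation). Of 23 early T progenitor genes 1 rose, Cd93, also when adjusted over the list alone (camera adjusted p = 0.00503, and adjusted p = 0.705 with an estimated correlation). None of 24 monocyte and macrophage genes passed over all genes, 9 were higher when adjusted over the list alone, and 24 of 24 were positive (camera adjusted p = 6.37e-07, and adjusted p = 0.705 with an estimated correlation). The monocyte level was 3.63, 2.92, 4.03 and 7.21 log2 CPM in the KO-ITD libraries, and without replicate 4 the list median fell from 3.22 to 1.03 (adjusted p = 0.000212). Camera also called the granulocyte, erythroid and megakaryocyte lists higher with no member passing either adjustment (adjusted p = 0.000888, 0.00365 and 0.00523, and 0.791, 0.791 and 0.705 with an estimated correlation). The granulocyte list did not pass without WT-ITD replicate 3 (adjusted p = 0.0656), the megakaryocyte list without WT-ITD replicate 2 (0.0573) and the erythroid list without KO-ITD replicate 2 or WT-ITD replicate 3 (0.172 and 0.265). The B cell (1 fell of 19), NK (0 of 18) and dendritic cell (0 of 20) lists did not pass, at adjusted p = 0.31, 0.31 and 0.802, and 0.955, 0.955 and 0.978 with an estimated correlation. Adjusted over the list alone 2 B cell genes were higher and 1 lower, 2 NK genes were higher and no dendritic cell gene passed. Of 18 stroma genes 1 rose, Pdgfrb, and 3 were higher when adjusted over the list alone (camera adjusted p = 0.00503, and adjusted p = 0.705 with an estimated correlation), and the median of that list fell from 2.78 to 1.29 without KO-ITD replicate 4. In all, 32 genes rose and 44 fell (edgeR), 73 of the 76 by at least 2-fold, and the planned limma test on FPKM called 38. DESeq2 called 1288, limma voom 185, edgeR on these 2 groups alone 0 (1526 with an unadjusted p below 0.05), the libraries of the first submission 246, tissue as a covariate 1088 and marrow libraries alone 586. Most calls were of falls on FPKM (12 rose, 26 fell) and in the first submission (87 and 159). They were of rises in DESeq2 (887 and 401), with tissue as a covariate (716 and 372) and in marrow alone (381 and 205), so no direction prevails. The count was 13, 10 and 501 without WT-ITD replicates 1, 2 and 3 and 641 and 131 without KO-ITD replicates 2 and 4. Of 20 named genes Cdh24 passed whichever library was left out.

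Dnmt3a loss in normal thymocytes was asked by setting KO-GFP (n = 2) against WT-GFP (n = 2). Dnmt3a was at 175.7 ± 44.5 against 253.7 ± 4.99 CPM (log2 fold change -0.53, SE 0.34), Dnmt3b at 10.2 ± 3.13 against 8.98 ± 0.49 CPM (0.19, SE 0.46), Cd4 at 1412 ± 201 against 1470 ± 269 CPM (-0.06, SE 0.32), Cd8a at 1701 ± 138 against 1805 ± 4.94 CPM (-0.09, SE 0.60) and Flt3 at 2.92 ± 0.52 against 2.75 ± 1.37 CPM (0.09, SE 0.74), each with an edgeR adjusted p of 1. The directions of Dnmt3b, Cd4 and Flt3 turned when single libraries were left out (Dnmt3b -0.17, Cd4 0.08 and Flt3 -0.11 without KO-GFP replicate 2; Cd4 0.14 and Flt3 -0.34 without WT-GFP replicate 2), and Cd4 was at 0.09 on quantile-normalised FPKM. No gene passed in edgeR, where 74 had an unadjusted p below 0.05, fewer than chance alone would give. The median SD of log2 CPM over genes was 0.122 in WT-GFP and 0.174 in KO-GFP, against 0.249 to 0.585 in the other groups with at least 2 libraries. The fit shares 1 estimate of the spread, so the lack of calls does not show that Dnmt3a loss has no effect. In a fit of these 2 groups alone, 1048 of 12388 genes had an unadjusted p below 0.05. The planned limma test on FPKM and limma voom also called 0, DESeq2 12 and edgeR on these 2 groups alone 3. At list level, 36 of 36 cell cycle genes and 26 of 32 interferon response genes had a positive log2 fold change, with a median of 0.40 and 0.41 (camera adjusted p = 3.52e-09 and 7.23e-06), and no member passed over all genes or over the list alone. Camera also called the granulocyte (adjusted p = 1.22e-07), erythroid (0.0472) and MYC target (0.0288) lists higher and the NK list lower (0.0288), again with no member called. With an estimated correlation, each of these 6 lists had an adjusted p of 0.999, and only the cell cycle and interferon lists passed whichever library was left out. The cell cycle median ran from 0.193 without WT-GFP replicate 2 (adjusted p = 0.0472) to 0.682 without WT-GFP replicate 1.

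In the knock-in model, Dnmt3a f/+ leukemias (n = 2) were set against pre-leukemic marrow (n = 3), so that genotype and disease stage differ together. Camera called the granulocyte list higher and the stem cell and interferon response lists lower in the leukemias, more so in replicate 2. None of the 3 passed with an estimated correlation (adjusted p = 0.508, 0.262 and 0.262). In Dnmt3a f/+ replicates 1 and 2 the granulocyte level was 6.66 and 9.35 log2 CPM (pre-leukemic 5.1, 5.22 and 4.59), the stem cell level 4.18 and 2.02 (5.32, 5.96 and 4.61) and the interferon level 3.22 and 2.46 (4.6, 4.73 and 4.22). Without replicate 2 the medians of these lists were 1.82, -0.511 and -1.35 (camera adjusted p = 0.0223, 0.0105 and 7.14e-06). Without replicate 1 they were 4.51, -3 and -1.92. The neutrophil genes Mmp9 (321 ± 405 against 1.23 ± 0.73 CPM, log2 fold change 8.27, SE 1.57, adjusted p = 0.018), Retnlg (7.94), Mmp8 (6.72) and Cd177 (6.37) rose. Slamf1, which encodes the stem cell surface protein CD150, fell from 23.8 ± 14.1 to 0.50 ± 0.10 CPM (-5.53, SE 0.60, adjusted p = 0.00177), with Pbx3 (-2.44). Dnmt3a fell from 142 ± 12 to 51.2 ± 5.37 CPM (-1.47, SE 0.32, adjusted p = 0.0267) and Tet1 from 91.6 ± 17.8 to 19.3 ± 2.04 CPM (-2.24, SE 0.33, adjusted p = 0.00843). Cd8a rose from 0.34 ± 0.32 to 4.11 ± 3.17 CPM (3.96, SE 0.83, adjusted p = 0.024), while Dnmt3b (-0.92, SE 0.43, adjusted p = 0.201), Flt3 (0.09, SE 0.64, adjusted p = 0.961, -0.58 without Dnmt3a f/+ replicate 1 and -0.07 without pre-leukemic replicate 3) and Cd4 (1.06, SE 0.38, adjusted p = 0.111) did not pass.

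Of 27 granulocyte genes 4 rose, 16 when adjusted over the list alone, and 27 of 27 were positive (camera adjusted p = 1.08e-06, and adjusted p = 0.508 with an estimated correlation). Of 34 stem and progenitor genes 4 fell, 8 when adjusted over the list alone (camera adjusted p = 3.28e-08, and adjusted p = 0.262 with an estimated correlation), including Tek, the angiopoietin receptor (-7.26). Of 32 interferon response genes 5 fell, 9 when adjusted over the list alone (camera adjusted p = 3.56e-10, and adjusted p = 0.262 with an estimated correlation), with Oas3 at -2.74, Ifih1 at -1.95, Ifit2 at -1.86 and Irf9 at -1.26. Of 20 immediate early and stress genes 3 rose, 7 when adjusted over the list alone (camera adjusted p = 0.000305, and adjusted p = 0.262 with an estimated correlation), with Ier2 at 1.55 and Klf6 at 2.06. Of 20 glycolysis genes 4 rose and 1 fell, 13 and 1 when adjusted over the list alone (camera adjusted p = 0.000444, and adjusted p = 0.419 with an estimated correlation), with the kinases Pkm at 1.08 and Pgk1 at 1.44 and the hexokinase Hk1 at -1.27. Of 15 megakaryocyte genes 2 fell, also when adjusted over the list alone (camera adjusted p = 0.000832, and adjusted p = 0.419 with an estimated correlation), and of 24 monocyte genes 1 rose, Clec4a2 (5.70), also when adjusted over the list alone (camera adjusted p = 0.00155, and adjusted p = 0.743 with an estimated correlation). Camera called the T cell leukemia (adjusted p = 0.0206), DNA methylation (0.0212), early T progenitor (0.0412) and B cell (0.0412) lists lower. With an estimated correlation these had an adjusted p of 0.262, 0.262, 0.622 and 0.743. Their members that rose and fell numbered 1 and 2, 1 and 2, 0 and 0, and 0 and 1, and adjusted over the list alone 1 and 4, 1 and 3, 0 and 0, and 0 and 1. The early T, T cell leukemia, monocyte, B cell and glycolysis lists did not pass without Dnmt3a f/+ replicate 2 (adjusted p = 0.343, 0.359, 0.255, 0.255 and 0.474), nor the methylation list without replicate 1 (0.158).

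The largest rises were the guidance cue Sema3a (count ratio 1310, 95% counting interval 234 to 51600), the cytokine Il10 (at least 96.6-fold over the group), Klra2 (964, 173 to 38100), the neutrophil granule gene Olfm4 (791, 218 to 6530), the formyl peptide receptor Fpr1 (697, 125 to 27600), Apoc2 (630, 113 to 24900), Gdf10 (log2 fold change 8.59) and Slfn4 (357, 98.4 to 2950). The 7 of these given as ratios or bounds rest largely on 1 leukemia. Without Dnmt3a f/+ replicate 1 the values were 59.1 for Sema3a and 3.28 for Il10. Without replicate 2 they were 72.9 for Klra2, 26.5 for Olfm4, 86.1 for Fpr1, 132 for Apoc2 and 41.9 for Slfn4. The largest falls were Slc6a15 (count ratio 167, 46.1 to 1390), Gdf3 (211, 58.1 to 1750), Trpc6 (103, 34.9 to 501, and 62.6 without pre-leukemic replicate 2), Tek, the eosinophil peroxidase Epx (-6.85), Efcc1 (-6.60), Sdpr (-6.48) and Tmem56 (-6.46). Myc (-1.27), Runx1 (-1.45) and the cyclin Ccnd1 (-3.75) fell, and the survival gene Mcl1 rose by 0.99 on the log2 scale. In all, 532 genes rose and 243 fell (edgeR, 596 of the 775 by at least 2-fold). DESeq2 called 2383 genes (1292 rose, 1091 fell), limma voom 711 (364 and 347) and edgeR on these 2 groups alone 157 (92 and 65). Rises outnumber falls in each, by a margin that depends on the test. The count was 65, 38 and 126 without pre-leukemic replicates 1, 2 and 3 and 1246 and 229 without Dnmt3a f/+ replicates 1 and 2. Of 44 named genes Tet1, Arpp21 (-5.26), Cd3d (count ratio 95.5, 16.7 to 3820), Slamf1 and Ier2 passed whichever library was left out.

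The single Dnmt3a f/f leukemia was set against the same pre-leukemic marrow (n = 3), with the spread of the other groups standing in for its own. Vcan, the proteoglycan versican of monocytes, was at 642 CPM against 0.52 ± 0.17 (log2 fold change 10.29, SE 1.02, adjusted p = 0.00251), and the fibronectin gene Fn1 at 4973 against 7.14 ± 8.19 CPM (9.51, SE 2.19, adjusted p = 0.0394). Tet1 was at 11.5 against 91.6 ± 17.8 CPM (-2.99, SE 0.47, adjusted p = 0.0108), Dnmt3a at 36.5 against 142 ± 12 CPM (-1.96, SE 0.44, adjusted p = 0.0367) and Cd4 at 4.72 against 1.03 ± 0.27 CPM (2.30, SE 0.42, adjusted p = 0.0179). Cd8a rose by 3.91 (SE 0.92, adjusted p = 0.0415), and Dnmt3b (-2.15, SE 0.60, adjusted p = 0.0719) and Flt3 (-1.04, SE 0.86, adjusted p = 0.52) did not pass. Arhgef37 (at least 329-fold over the group), Apoc2 (count ratio 1620, 95% counting interval 290 to 64100), the collagenase Mmp13 (1400, 250 to 55300), Klra2 (927, 166 to 36700), Fpr1 (901, 161 to 35600) and Mmp9 (log2 fold change 9.25) were the other largest rises. The largest falls were Rab6b (-6.46), Arpp21 (count ratio 63.1, 17.3 to 524), the costimulatory receptor Cd27 (-4.94), Tbxa2r (-4.85), Eya2 (-4.73), Plxna3 (-4.65), Gimap1 (-4.62) and Mex3a (-4.51).

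Of 24 monocyte and macrophage genes 1 rose, Clec4a2 (5.87), 17 when adjusted over the list alone (camera adjusted p = 4.97e-10), and of 27 granulocyte genes 4 rose, 15 when adjusted over the list alone (camera adjusted p = 1.5e-09), each with adjusted p = 0.527 with an estimated correlation. Of 34 stem and progenitor genes 2 fell, Slamf1 (-4.38) and Sox4 (-2.94), 8 when adjusted over the list alone (camera adjusted p = 1.07e-09, and adjusted p = 0.464 with an estimated correlation). Of 32 interferon response genes 1 fell, the RNA sensor Ddx58 (-1.83), also when adjusted over the list alone (camera adjusted p = 3.56e-06, and adjusted p = 0.527 with an estimated correlation). Of 20 immediate early genes 2 rose, Ier2 (1.24) and Klf6 (2.28), 6 when adjusted over the list alone (camera adjusted p = 0.00015, and adjusted p = 0.464 with an estimated correlation). None of 28 MYC targets passed either adjustment, 27 of 28 were negative, and camera called the list lower (adjusted p = 0.00015, and adjusted p = 0.601 with an estimated correlation), while Myc itself fell by 1.77. Camera also called the NK, apoptosis and glycolysis lists higher (adjusted p = 0.0163, 0.0229 and 0.0358, and 0.601, 0.589 and 0.601 with an estimated correlation). In these 1 NK gene and 2 of 22 apoptosis genes rose, with the same counts when adjusted over the list alone, and 2 of 20 glycolysis genes fell, with 9 higher and 3 lower when adjusted over the list alone. In all, 327 genes rose and 140 fell (edgeR, 439 of the 467 by at least 2-fold). DESeq2 called 1819 (882 rose, 937 fell), limma voom 881 and edgeR on these 2 groups alone 3676. The apoptosis and glycolysis lists did not pass without pre-leukemic replicate 2 (adjusted p = 0.0535 for both). The count of genes was 44, 36 and 91 without pre-leukemic replicates 1, 2 and 3. Of 37 named genes Vcan, Arpp21, Tet1, Cd3d (count ratio 148, 25.8 to 5900) and Slamf1 passed whichever of these was left out.

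The Dnmt3a f/f leukemia (n = 1) against the Dnmt3a f/+ leukemias (n = 2) asks whether the second Dnmt3a allele makes a difference. Dnmt3a was at 36.5 against 51.2 ± 5.37 CPM (log2 fold change -0.49, SE 0.42, edgeR adjusted p = 0.728), and Dnmt3b (-1.23, SE 0.59), Flt3 (-1.13, SE 0.90), Cd4 (1.24, SE 0.42) and Cd8a (-0.06, SE 0.80) did not pass either, at adjusted p = 0.574, 0.708, 0.507 and 1. Cd8a was at 0.01 under DESeq2's size factors and in DESeq2, 0.17 in limma voom and 1.09 without Dnmt3a f/+ replicate 1. No gene passed in edgeR, where 1352 had an unadjusted p below 0.05 and the smallest adjusted p was 0.0547. Limma voom also called 0 and DESeq2 210, and without Dnmt3a f/+ replicate 2 edgeR called 390. At list level, 21 of 23 erythroid, 23 of 24 monocyte, 32 of 36 cell cycle and 10 of 15 megakaryocyte genes were positive and 25 of 28 MYC targets negative. Camera called these 5 lists (adjusted p = 3.69e-06, 1.69e-05, 0.000623, 0.0102 and 0.0102, and 0.885 for each with an estimated correlation), with no member passing over all genes and 1 megakaryocyte gene passing over its list alone. The MYC target list did not pass without Dnmt3a f/+ replicate 1 (0.983), nor the megakaryocyte and cell cycle lists without replicate 2 (0.216 and 0.0604).

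The models were compared by setting KO-ITD leukemias (n = 4) against the knock-in leukemias (mean of the Dnmt3a f/+ and f/f groups, n = 3). These differ in model, sort and Cre driver (Mx1-cre against ER-cre). They differ in tissue only for KO-ITD replicates 3 and 4, from thymus, as the other libraries came from marrow. The knock-in libraries are all of the second submission. Rag1, the recombinase of antigen receptor genes, was at 1866 ± 1472 against 0.10 ± 0.10 CPM (log2 fold change 14.02, SE 1.59, adjusted p = 8.78e-05), and Cd4 at 301 ± 90.3 against 2.90 ± 1.57 CPM (6.61, SE 0.39, adjusted p = 7.97e-07). Cd8a (7.04), Cd3d and Ptcra, the pre-T cell receptor alpha chain (count ratio 6950, 95% counting interval 2380 to 33700), were higher as well. Myeloperoxidase, Mpo, was at 8.82 ± 7.46 against 3115 ± 1874 CPM (-8.55, SE 1.06, adjusted p = 0.000163) and neutrophil elastase, Elane, at 3.11 ± 2.17 against 938 ± 699 CPM (-8.32, SE 1.05, adjusted p = 0.000188). Flt3 (chromosome 5, 148142317 to 148212065) was at 1.82 ± 1.24 against 178 ± 106 CPM (-6.36, SE 0.66, adjusted p = 4.5e-05). Its mean was no higher in KO-ITD than in KO-GFP, although KO-ITD carries the FLT3-ITD transgene. Whether the Flt3 count includes transgene reads is not given, so this value does not compare total FLT3 between the models. The homeobox gene Hoxa9 was lower at a count ratio of 588 (105 to 23200, and 351 without Dnmt3a f/+ replicate 1), and Dnmt3a was higher by 0.86 (SE 0.27, adjusted p = 0.0398), with overlapping libraries. Dnmt3b did not pass (0.77, SE 0.37, adjusted p = 0.149).

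Of 38 genes of double-positive thymocytes 35 were higher and none lower, over all genes and when adjusted over the list alone, with a median log2 fold change of 6.05 (camera adjusted p = 4.08e-60, and adjusted p = 0.000449 with an estimated correlation). Of 16 Notch targets 9 were higher and 1 lower, 12 and 1 when adjusted over the list alone (camera adjusted p = 1.05e-05, and adjusted p = 0.322 with an estimated correlation), with Il2ra at 9.20 and Notch3 at 7.37. Of 27 granulocyte genes 19 were lower, 21 lower and 1 higher when adjusted over the list alone (camera adjusted p = 5.46e-11, and adjusted p = 0.522 with an estimated correlation), with Ms4a3 at -7.62 and Prtn3 at -6.90. Of 34 stem and progenitor genes 11 were lower and 3 higher, 14 and 3 when adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.629 with an estimated correlation), with Hoxa7 at a count ratio of 258 (71 to 2130, and 150 without Dnmt3a f/+ replicate 1) and Slamf1, which is also a lymphocyte receptor, higher by 6.23. Of 20 glycolysis genes 12 were lower, 13 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.44e-05, and adjusted p = 0.522 with an estimated correlation), with Hk2 at -3.05, Aldoa at -2.08 and Pgam1 at -1.97. Among transcription factors linked to T cell leukemia, Lef1 (7.86) and Bcl11b (6.74) were higher and Lmo1 (-7.35) lower. Of the methylation genes, Tet1 (1.26) was higher and Tet2 (-2.80) lower. Camera also called the interferon response (7 higher, 1 lower of 32), B cell (5 higher of 19) and p53 target (6 higher, 1 lower of 24) lists higher, at adjusted p = 0.00995, 0.0355 and 0.0422, and 0.638 for each with an estimated correlation. The B cell and p53 lists did not pass in 3 of the fits that leave out 1 library, nor the interferon list without KO-ITD replicate 4 (adjusted p = 0.0613). The monocyte (1 higher, 5 lower of 24) and mature T cell (4 higher, 1 lower of 20) lists did not pass, at adjusted p = 0.072 and 0.614, and 0.755 and 0.893 with an estimated correlation, with 2 and 5 and 5 and 1 when adjusted over the list alone. Camera called the megakaryocyte (6 lower of 15) and early T progenitor (6 higher, 11 lower of 23) lists lower, at adjusted p = 0.00138 and 0.00754, and 0.557 for both with an estimated correlation. Adjusted over the list alone, the counts were the same for the interferon and B cell lists, 8 higher and 2 lower for p53 targets, 8 lower for megakaryocyte genes, and 6 higher and 12 lower for early T progenitor genes.

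The other largest rises were Vwce (at least 936-fold over the group), Olig3 (at least 1020-fold), the transporter Slc16a5 (count ratio 7730, 95% counting interval 1390 to 305000), the mast cell tryptase Tpsb2 (at least 523-fold), Gpr83 (3120, 864 to 25800) and Kcnh3 (4320, 775 to 171000). The other largest falls were Clec4b2 (at least 115-fold lower), Ptprr (at least 71.6-fold lower), Gpr141 (-9.36), Kcnk12 (554, 99.1 to 21900) and Abcc2 (309, 55.1 to 12200). Leaving out 1 library lowered Vwce to 453 (KO-ITD replicate 4), Slc16a5 to 5110 (KO-ITD replicate 2), Tpsb2 to 292 (KO-ITD replicate 1), and Clec4b2 and Ptprr to 73.8 and 44 (Dnmt3a f/+ replicate 2). In all, 1687 genes were higher and 1640 lower (edgeR, 2575 of the 3327 by at least 2-fold), against 1707 and 2271 in limma voom. The Dnmt3a f/f library was not left out, as its group has no other. Of 54 named genes 49 passed in all 6 fits that leave out 1 of the other libraries. EdgeR on these groups alone called 662 genes, and within the second submission alone 897, where Rag1 (12.82), Cd4 (6.86) and Mpo (-9.08) passed and Dnmt3a (0.50, adjusted p = 0.203) and Tet1 (1.14, adjusted p = 0.0761) did not.

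**Figure D3:**
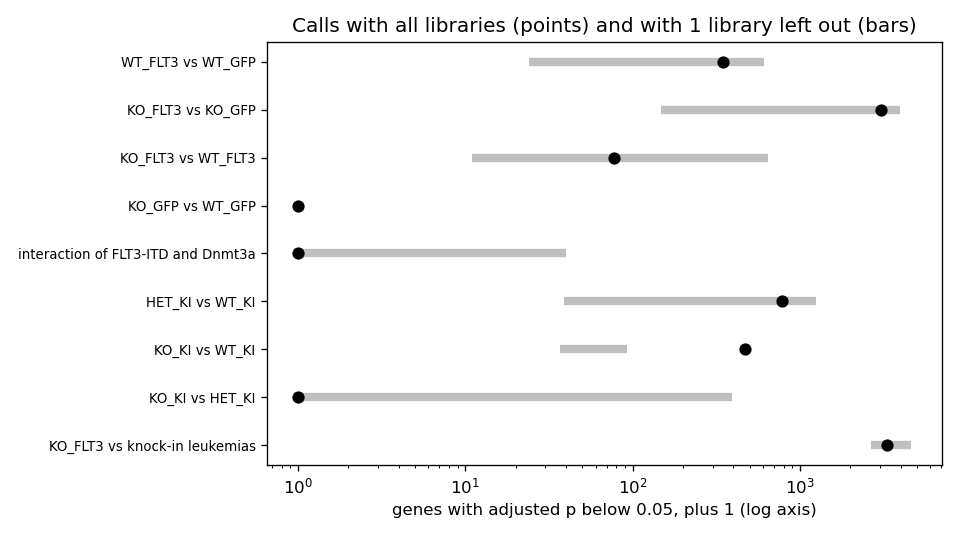
Number of genes past the threshold in edgeR (count plus 1, log axis) for each comparison: points are the counts with all libraries and bars span the counts when each library is left out in turn, except the only Dnmt3a f/f library, which was kept. The bar of WT-ITD against WT-GFP runs from 23 to 607 genes and that of KO-ITD against KO-GFP from 147 to 3954.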

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

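In this part, the tests of marrow libraries for stroma genes and of the spread of the WT-ITD libraries were chosen after the results were seen. Among 76 values tested in KO-ITD, the only group of at least 4 libraries, 11 had 1 library far from the other 3 (gap to the nearest library over the whole range, above Dixon's 95% critical value), and chance gives such a ratio in about 1 in 20 groups. KO-ITD replicate 4 stood apart in the level of FLT3, STAT5 or MAPK targets (ratio 0.844) and of stem and progenitor genes (0.906), and replicate 2 in that of erythroid genes (0.89) and in total count (0.914). For single genes the ratio was 0.846 for Lmo4, high in replicate 4. It was 1 for Abcc2 and Hoxa9 (replicate 1), Clec4b2 and Ptprr (replicate 4), Kcnk12 (replicate 2) and Wnt8b (replicate 3), genes with no or few counts, where the value reflects depth or 1 library with counts. KO-ITD replicate 4 also had the lowest cell cycle level (4.98 log2 CPM, others 6.98 to 7.46) and the highest monocyte level (7.21, others 2.92 to 4.03).

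In the interaction of FLT3-ITD with Dnmt3a loss, camera called 8 lists whose median differed from 0 and none of whose genes passed over all genes. The medians were -0.453 for genes of double-positive thymocytes, 1.32 for early T progenitors, 3.13 for monocytes and macrophages, 1.78 for megakaryocytes, 0.972 for NK cells, -0.326 for the cell cycle, 0.438 for p53 targets and -0.589 for the interferon response. With an estimated correlation none passed (adjusted p from 0.728 to 0.93), and 6 of the 8 were lost in at least 1 fit that leaves out a library. The monocyte list, which was not lost, had a median of 1.00 without KO-ITD replicate 4.

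Of 18 genes of thymic stroma, 8 rose in KO-ITD against KO-GFP, and the list had a median log2 fold change of 4.32, also with 3 genes at their bound (camera adjusted p = 0.014, but 0.813 with an estimated correlation, so a change of the list as a whole is not established). Without KO-ITD replicate 4, the library with the highest stroma level, the median was 4.00, which argues against RNA of stromal cells in KO-ITD replicate 4 as the whole cause. The thymus libraries lay above the marrow libraries by at least 1.67 log2 units, so collection from the thymus may account for the spread among the KO-ITD libraries, from 2 libraries of each tissue. The thymus libraries are also those of the second submission, so tissue and submission cannot be told apart here. The marrow libraries lay at least 1.37 above KO-GFP, which came from thymus. Collection from the thymus could not explain that excess whatever its size, so this value does not test it. A CD4+CD8+ sort should remove stromal cells, yet Col1a1 reached 513 CPM. A change in the leukemic cells themselves, the donor enrichment (Sca-1 in KO-ITD, ckit in KO-GFP) and the sex of the animals stay open and untested. So does, for the marrow libraries, collection from marrow instead of thymus.

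KO-ITD against KO-GFP had 8.78 times as many calls as WT-ITD against WT-GFP. With 3 instead of 4 KO-ITD libraries there were still at least 2321 calls, and within the first submission the ratio was 2.87. Each of these values argues against its explanation (the number of leukemia libraries, the second submission) as the whole cause. The spread of WT-ITD was 0.57 times that of KO-ITD. The fit shares 1 spread per gene, so a larger spread among WT-ITD would enter both counts, and this value does not test it as a cause. In fits of only the groups compared, the count for KO-ITD against KO-GFP was however 439, against 904 for WT-ITD against WT-GFP. The excess was reversed there, so it depends on which libraries are fitted together. The interaction, which tests the difference itself, had 0 genes past the threshold in edgeR (838 at an unadjusted p below 0.05), 0 in limma voom and 80 in DESeq2, so a difference between genotypes is not shown by the ratio.

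Of the 35 splits of the 7 FLT3-ITD leukemias into 4 and 3, 3 gave at least as many calls as the 76 between KO-ITD and WT-ITD, so chance is not excluded. The highest other split, KO-ITD replicates 1, 3 and 4 against KO-ITD replicate 2 with WT-ITD, gave 1161. It moves only KO-ITD replicate 2 across the genotypes, and without that library KO-ITD against WT-ITD had 641 calls. The remaining split, KO-ITD replicates 3 and 4 with WT-ITD replicate 3 against the rest, mixed the genotypes and gave 794. What sets these libraries apart was not tested. For KO-ITD against the knock-in leukemias, the splits take the Dnmt3a f/+ and f/f leukemias as 1 group, unlike the mean of 2 groups that gave 3327 calls. Only 1 of 35 splits, the real one with 3485 calls, gave as many. The highest other, which moved KO-ITD replicate 4 to the knock-in side, gave 2924. Ranking first is the strongest result that 35 splits can give, and it does not by itself exclude chance.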

How the results depend on the processing

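DESeq2 and its size factors for the retroviral comparisons, limma voom, a minimum of 5 CPM, counts of the 9 libraries of the first submission and the second submission alone were chosen after seeing the data. Counts of genes past the threshold stayed within 1.5 times their value in every comparison under DESeq2's size factors, without a filter and with a minimum of 5 CPM. DESeq2 gave 1425 (WT-ITD against WT-GFP), 5015 (KO-ITD against KO-GFP), 1288 (KO-ITD against WT-ITD), 12 (KO-GFP against WT-GFP), 80 (interaction), 2383 (Dnmt3a f/+ against pre-leukemic), 1819 (Dnmt3a f/f against pre-leukemic) and 210 (Dnmt3a f/f against f/+). Limma voom gave 876, 185 and 881 for WT-ITD against WT-GFP, KO-ITD against WT-ITD and Dnmt3a f/f against pre-leukemic. A fit of only the groups compared, with fewer samples for the spread, gave 904, 439, 0, 3, 157, 3676 and 662 for WT-ITD against WT-GFP, KO-ITD against KO-GFP, KO-ITD against WT-ITD, KO-GFP against WT-GFP, f/+ and f/f against pre-leukemic, and KO-ITD against the knock-in leukemias. For that last comparison the second submission alone gave 897. The counts of the 9 libraries of the first submission gave 1268 for WT-ITD against WT-GFP, 246 for KO-ITD against WT-ITD and 13 for the interaction. Tissue as a covariate gave 1088 and bone marrow libraries 586 for KO-ITD against WT-ITD, and thymus libraries 184 for WT-ITD against WT-GFP. Limma on FPKM, over 3914 genes, gave 958 for KO-ITD against KO-GFP and 38 for KO-ITD against WT-ITD. With a pseudocount of 0.1 it gave 901, 32 and 2 (KO-GFP against WT-GFP). Without a filter it gave 685, 4 (KO-GFP against WT-GFP) and 3 (interaction), with a minimum of 5 it gave 861 and 31, and with quantile normalization 1173 and 1 (KO-GFP against WT-GFP). Except for fits on fewer genes or samples, the cause was not tested.

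Leaving out each library in turn, except the only f/f library, the counts ran from 23 to 607 (WT-ITD against WT-GFP), 147 to 3954 (KO-ITD against KO-GFP), 10 to 641 (KO-ITD against WT-ITD), 0 to 39 (interaction), 38 to 1246 (f/+ against pre-leukemic), 36 to 91 (f/f against pre-leukemic) and 0 to 390 (f/f against f/+). The number of gene lists called by camera ran from 6 to 10 (WT-ITD against WT-GFP), 7 to 11 (KO-ITD against WT-ITD), 4 to 12 (interaction) and 8 to 10 (f/f against f/+). Of the lists called with all libraries, those lost in at least 1 of these fits numbered 1 of 6 (WT-ITD against WT-GFP), 3 of 12 (KO-ITD against KO-GFP), 3 of 7 (KO-ITD against WT-ITD), 4 of 6 (KO-GFP against WT-GFP) and 6 of 8 (interaction). They numbered 6 of 11 and 2 of 9 (f/+ and f/f against pre-leukemic), 3 of 5 (f/f against f/+) and 3 of 10 (KO-ITD against the knock-in leukemias). Camera with an estimated correlation called 0 gene lists in 8 comparisons and 1 in KO-ITD against the knock-in leukemias, the genes of double-positive thymocytes.

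Values of named genes kept direction and side of the threshold in 3029 cases, lost the call in 808, gained it in 12 and turned in 21. Those that turned, the cause not being tested, were as follows. Cd8a in f/f against f/+ was at 0.01 under DESeq2's size factors (RLE), 0.01 in DESeq2, 0.17 in limma voom and from -0.68 to 1.09 with libraries left out. Flt3 in KO-ITD against WT-ITD was at 0.02 in bone marrow libraries. Dnmt3b in KO-ITD against WT-ITD was at 0.2 in the 9 libraries of the first submission and from -0.38 to 0.01 with libraries left out, and in the interaction at 0 and from -0.62 to 0.01. In KO-GFP against WT-GFP, Cd4 was at 0.09 on FPKM with quantile normalization and from -0.23 to 0.14 with libraries left out, Dnmt3b from -0.17 to 0.47 and Flt3 from -0.34 to 0.71. Flt3 ran from -0.58 to 0.55 in f/+ against pre-leukemic and from -0.33 to 1.13 in WT-ITD against WT-GFP. Of called genes, Gapdh in KO-ITD against KO-GFP was at -0.09 on FPKM with quantile normalization, and Epcam in f/+ against pre-leukemic ran from -1.53 to 5.97.

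The same replicate numbers recur across groups, and libraries with the same number correlated at -0.287 to 0.369 after group means were removed. Libraries with different numbers were not compared, so these values do not settle whether the numbers pair samples. With a replicate block, WT-ITD against WT-GFP had 567 genes past the threshold and Dnmt3b in KO-ITD against WT-ITD was at 0.01. Depth limits the KO-ITD replicates 1, 3 and 4 and the pre-leukemic replicates 1 and 2 most, with total counts of at most 8597919.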

Other observations

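The comparison of both models in this part was chosen after the results were seen. Stroma genes differed among libraries that all had the CD4+CD8+ sort, and neither tissue nor group alone ordered them. Their mean level was 2.06, 1.57, 3.73 and 5.24 log2 CPM in KO-ITD replicates 1 to 4, 0.55, -0.41 and 2.83 in WT-ITD replicates 1 to 3, and -0.09 to 0.20 in the GFP libraries. Col3a1, another fibroblast collagen of that list, was chosen after its values were seen: it was at 9.42, 5.61, 59.29 and 667.59 CPM in the KO-ITD libraries and 0.98, 0.06 and 31.06 CPM in WT-ITD. The granulocyte list was at 4.12, 0.09 and 0.75 log2 CPM and the erythroid list at 4.87, 1.11 and 0.68 in WT-ITD replicates 1 to 3, so that 1 thymus library carried most of these transcripts.

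Dnmt3a f/+ leukemias against pre-leukemic marrow and KO-ITD against WT-ITD both compare lower with higher Dnmt3a. Of 775 genes called in the first, 534 (68.9%, 95% interval 65.5% to 72.1%) had the same sign in the second, against 58.4% of genes not called, and genes are not independent. Both called 11 genes, against 3.8 expected of independent calls, and 10 went the same way: AA467197, Arhgef3, Dnmt3a, Ephb6, Itpkb, Kansl1l, Mum1l1, Nfil3, Pde4b and Tet1. Dnmt3a is the gene targeted in both, so its shared fall is no evidence. Both comparisons come from 1 fit with the same spread per gene, so their calls are not fully independent. Nfil3 rose by 2.24 and 2.74, Tet1 changed by -2.24 and -1.41, and Vegfa went opposite ways (2.25 and -1.55). A shared direction across the 2 models (68.9%) can be read as an effect of lower Dnmt3a, but the knock-in comparison also sets leukemia against pre-leukemic marrow. Among lists that camera called in both comparisons, the granulocyte (medians 3.62 and 0.887) and monocyte (1.67 and 3.22) lists were higher in both. The megakaryocyte (-1.53 and 1.61) and early T progenitor (-0.528 and 1.11) lists went opposite ways. No test separates lower Dnmt3a from disease stage or from a shared rise of myeloid transcripts.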
